A study of Homo sapiens with 14 samples.

How the data were processed

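RNA was measured in MCF7ras cells, a human breast cancer line, in a control line (ctrl) and in a tetO-SOX9 line. Both lines received doxycycline at 2 µg/ml for 3 days, under which the tetO-SOX9 line overexpresses SOX9 (SOX9OE), per the labels' protocols. The 6 RNA libraries formed 2 groups of 3. SOX9 chromatin immunoprecipitation followed by sequencing (ChIP-seq) and its input DNA made up 8 more samples, 2 for each of ctrl input, ctrl SOX9 ChIP, SOX9OE input and SOX9OE SOX9 ChIP. The deposited ChIP data were 2 peak lists, so the ChIP and input libraries were not analysed one by one.

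For RNA, non-stranded paired-end libraries with reads of 150 bases were sequenced, per the labels' protocols. Reads were aligned with STAR 2.4.0, per the submitters' processing notes, which give the build as GRCh38.p13. The deposited values are raw counts of reads per gene, made with featureCounts 1.5.0-p1 on the GENCODE 33 annotation, per the file headers. The command line in those headers counts without strand, treats the mates of a pair as separate reads and leaves out reads that map to several places or overlap several genes. A gene that shares exons with a neighbour, or sequence with a paralog, therefore loses reads. Counts of mates overstate the number of independent fragments. The processing notes also name DESeq2 1.30.1, and no result of it was used here.

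For ChIP-seq, an antibody against SOX9 was used on chromatin sheared to 100 to 600 bp, with 5% mouse chromatin added as a spike-in, per the labels' protocols. The processing notes name Bowtie2 2.4.2, Genrich 0.6.1 and deepTools 3.5.0, and the build hg38. The deposited peak lists hold a score per peak, the signal value, which in the output of Genrich is the area under the curve of significance. They also hold, as deposited, −log10 p and −log10 q for each peak. The lowest signal value lay just above 10 in both lists. One list was deposited for SOX9OE SOX9 ChIP over SOX9OE input and the other for SOX9OE SOX9 ChIP over ctrl SOX9 ChIP, as the deposited names state. Whether replicates were pooled, and whether the spike-in was used for scaling, are not given in the sources used here.

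Of the 60662 genes in the tables, 42009 had a symbol in the gene name table and 40206 a biotype. Genes were kept with the edgeR filter filterByExpr (minimum count 10, minimum total count 15), which left 19259. Library sizes were scaled by the trimmed mean of M values (TMM) and the groups were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust dispersion estimates and group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and the threshold was an adjusted p under 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. Levels are given as TMM-normalised CPM (library-scaled counts), mean ± SD over 3 libraries. A gene at 0 counts in all ctrl libraries was set to a floor of 3 counts per library, and its fold is given as a lower bound. Intervals and floors cover counting error only, and treat the mates of a pair as independent.

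For gene lists, 35 lists with 805 symbols were fixed before the data were examined, as were the tests, the thresholds, most of the other settings tried and the rule for named genes. SOX9 was left out of the lists because it is the transgene. The lists covered immune ligands and antigen presentation, interferon, cytokine and NF-kappaB genes, breast lineage markers, mesenchymal, junction, cartilage, SOX, stem cell, Wnt, YAP, Notch, TGF-beta, MAPK and AP-1 genes, cell cycle, p53, stress, hypoxia, cholesterol, respiration and mucin genes, and markers of fibroblasts, leukocytes, endothelium, neural crest and hair follicle or intestine. Of the symbols, 1 matched no gene, and 54 genes stood in more than 1 list. The 34 lists with at least 5 tested members were compared with all other genes by camera of limma 3.58.1 with a preset correlation between genes of 0.01. Camera was repeated with a correlation estimated per list, and fry was run beside it, which tests whether the members of a list move one way without comparing them with other genes. List p-values were adjusted over the 34 lists, and the estimated correlation values likewise. List values given with DESeq2 or its Wald test come from camera run on the Wald statistics of the genes (cameraPR), not on log expression. They therefore differ from the main list test in its input as well as in the gene test.

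The named genes were SOX9 and VTCN1, the 12 largest rises and 12 largest falls among protein-coding genes past the threshold with a mean log2 CPM of at least 2 and no overlap between groups, and up to 4 members of each list by smallest adjusted p. For peaks, the rule named those within 100 kb of the transcription start site (TSS) of VTCN1 or SOX9, the 5 with the highest signal in each list, and the 8 higher and 8 lower genes by smallest adjusted p with a summit within 10 kb and a mean log2 CPM of at least 2.

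Peaks were compared with bedtools 2.31.1 and GenomicRanges 1.54.1. Peaks sharing at least 1 bp counted as overlapping, and 100 seeded shuffles within chromosomes served as the background. The TSS of a gene was its 5′ end in the coordinates of the count tables. Peak positions were set against 20 draws of random positions in the same chromosomes. Assembly gaps were to be left out of these draws, but no genome sequence was at hand, so random positions include gaps. The presence of a summit within 10 kb of a TSS was compared between changed genes and genes not past the threshold in a logistic model with mean log2 CPM and log10 gene span as covariates. Intervals for shares are 95% Wilson intervals. A planned search for SOX motifs under the summits needed the genome sequence and was not run.

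The gene test was checked on simulated counts for SOX9OE against ctrl with 18710 genes tested and 200 genes changed. It recovered 52.2% of the 1.5-fold changes, 85.7% of the 2-fold changes and 96.8% of the 4-fold changes, and 13 of its 162 calls, 8.02%, were false. In the simulated data the list test called the 1 list that was moved and no other list, and a true odds ratio of 2 was estimated as 1.95 (1.81 to 2.10). The simulated genes were drawn independently of each other and few were changed. In the real data most tested genes were called, and the estimated correlation within a list reached 0.657 (G2/M). The checks therefore do not cover the list test with correlated genes, or the gene test and scaling under widespread change.

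Depth was 38746454 to 50319170 counts per library. Alternatives covered the scaling, the test (DESeq2 1.42.0 and limma-voom), the low-count filter, the gene classes, each left-out library, thresholds, list tests, peak thresholds, overlap rules and windows around the TSS.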

Results

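Gene expression was measured by RNA-seq in MCF7ras cells, a RAS-expressing derivative of the MCF-7 breast cancer line, as a control line (ctrl, 3 libraries) and as a line with a doxycycline-inducible SOX9 transgene (SOX9OE, 3 libraries). SOX9 is an HMG-box transcription factor. Both groups received doxycycline, so the drug itself did not separate them. The ctrl libraries held 47024979, 50319170 and 49466152 gene counts for replicates 1 to 3, and the SOX9OE libraries 41367599, 38746454 and 44147725. SOX9 binding was measured by ChIP-seq in the same 2 lines. It was available here as 2 peak lists for SOX9OE cells, with 11075 peaks called over SOX9OE input and 12207 called over ctrl SOX9 ChIP.

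The RNA comparison asked which genes change when SOX9 is overexpressed, with VTCN1 (B7x, also B7-H4), an immune checkpoint ligand of the B7 family, as the gene the series title places downstream. SOX9 itself (ENSG00000125398.8; GRCh38 chromosome 17, 72121020 to 72126416) stood at 7.74 ± 0.940 CPM in ctrl and 956 ± 180 CPM in SOX9OE (SD, n = 3 each), a log2 fold change of 6.95 (SE 0.18, adjusted p = 7.9e-10). All 3 SOX9OE libraries lay above all 3 ctrl libraries, in the direction the labels give. The counts do not separate transcripts of the transgene from those of the resident gene. VTCN1 (ENSG00000134258.17; chromosome 1, 117143587 to 117210960) rose from 0.610 ± 0.279 to 47.1 ± 3.85 CPM (SD, n = 3 each), a log2 fold change of 6.26 (SE 0.19, adjusted p = 4.5e-13), on 90 ctrl counts and 5814 SOX9OE counts in all. P-values here measure only the spread between these libraries, since nothing in the labels says whether the replicates were separate cultures.

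**Figure D1:**
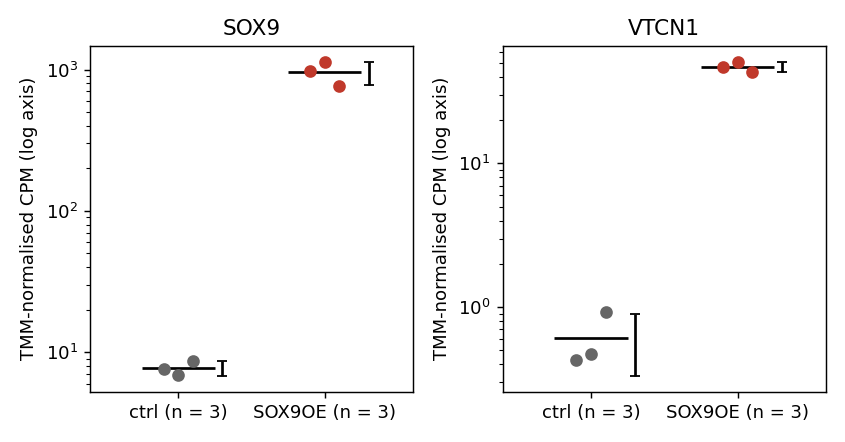
TMM-normalised CPM (log axis) of SOX9 and VTCN1 in each ctrl and SOX9OE library (points, n = 3 per group) with the group mean and SD. SOX9 means were 7.74 and 956 CPM and VTCN1 means 0.610 and 47.1 CPM, with no overlap between the groups.

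SOX9OE cells differed from ctrl cells across most of the expressed genome. Of 19259 genes tested, 6418 (33.3%) were higher and 6259 (32.5%) lower in SOX9OE. At least a 2-fold change was seen in 3285 of the higher and 3031 of the lower genes, and at least a 4-fold change in 1589 and 1156. The per-library values of the groups did not overlap in 13568 genes (70.5%), where chance alone gives 10% for 3 against 3. Correlations of log expression were 0.984 to 0.989 between libraries of a group and 0.881 to 0.890 between groups. Against a 1.5-fold minimum change (glmTreat), 3704 genes were higher and 3499 lower.

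The largest rises included genes with no detectable ctrl expression. DCLK1, a microtubule-associated kinase, had 0 ctrl counts and 18.3 ± 4.03 CPM in SOX9OE, at least 298-fold higher. SLC17A4, an anion transporter, was at least 226-fold higher and GAS7, a growth-arrest gene, at least 165-fold higher on the same floor of 3 counts per library. Mates of a pair were counted as separate reads, so bounds on this floor may be up to 2 times too high and counting intervals too narrow. MRGPRX4 had 2 ctrl counts and a ratio of 3919 (counting interval 1084 to 32366), and BICC1, an RNA-binding protein, also had 2 and a ratio of 1688 (467 to 13949). SPP1, which encodes the matrix protein osteopontin, rose by a log2 fold change of 11.59 (SE 0.49) to 638 ± 167 CPM. The myelin proteins PMP2 (9.93, SE 0.14) and MOBP (9.93, SE 0.64), the Wnt potentiator RSPO3 (9.45, SE 0.28), ANKRD30BL (9.53, SE 0.19), TMEM100 (9.29, SE 0.26) and LIX1 (9.25, SE 0.51) completed the 12 largest rises. The call for MOBP was lost in limma-voom (adjusted p = 0.0519).

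Among the largest falls were GATA4, a transcription factor (−6.57, SE 0.30), MSLN, which encodes mesothelin (−6.16, SE 0.28), DSCAM, a cell adhesion molecule (−6.09, SE 0.20), and CYP4F22, a fatty acid hydroxylase (−6.05, SE 0.14; 53.5 ± 6.30 to 0.809 ± 0.0464 CPM). GJA1, the gap junction protein connexin 43 (−5.40, SE 0.25), CRISP3 (−5.36, SE 0.32), the Hedgehog effector GLI1 (−5.34, SE 0.27), the chemokine receptor ACKR3 (−5.31, SE 0.17), the cytokine IL20 (−5.30, SE 0.15) and RCN3 (−5.26, SE 0.23) also fell. AQP1, a water channel, fell by 6.96 on the log2 scale, but 26.5% of its exonic bases overlap another gene. TUBA3E fell by 6.88, and reads of this tubulin gene may be lost to or shared with its paralogs.

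**Figure D2:**
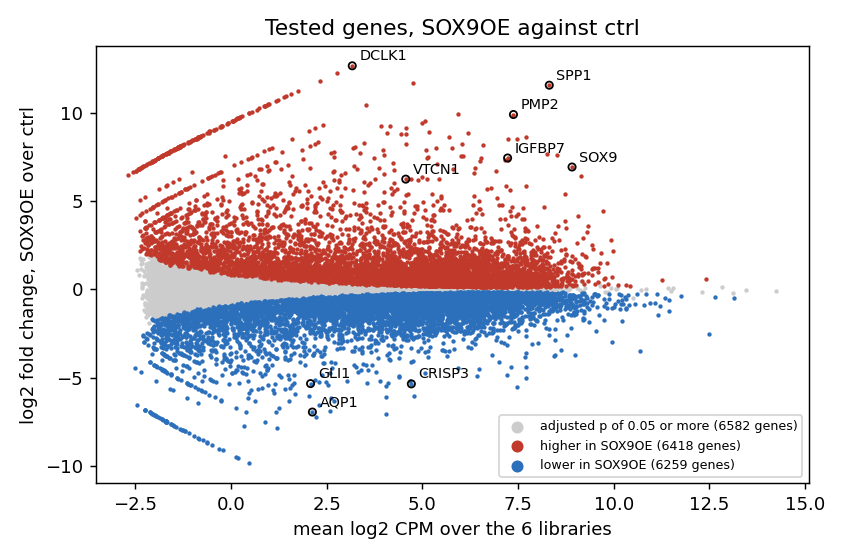
Log2 fold change of SOX9OE over ctrl (vertical axis) against mean log2 CPM over the 6 libraries for each of the 19259 tested genes (1 point each), with 6418 higher, 6259 lower and 6582 not past the threshold. Diagonal streaks are genes with few or no counts in a group, whose fitted fold is not a bound.

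Luminal identity genes fell in SOX9OE. Of 29 tested mature luminal markers, 23 fell and 4 rose (camera adjusted p = 5.8e-06, and adjusted p = 0.189 with an estimated correlation). The receptor ERBB3, which also stands in the neural crest and glial list, was among the 4 that rose. ESR1, the estrogen receptor, fell from 387 ± 9.21 to 27.4 ± 0.575 CPM, a log2 fold change of −3.82 (SE 0.06). The secretory transcription factor SPDEF (−4.41, SE 0.08) and the luminal keratin KRT18 (−3.52, SE 0.08) fell with it. Of 40 estrogen response genes, 36 fell and 4 rose (camera adjusted p = 2.9e-11), the 1 list whose call held with an estimated correlation (adjusted p = 0.0400). Its largest falls among named members were CXCL12, a chemokine (−4.91, SE 0.08), MYC (−4.53, SE 0.08) and ELOVL2, a fatty acid elongase (−4.05, SE 0.10). Of 11 mucin and secretory epithelium genes, 9 fell, among them AGR2 (−3.11, SE 0.12) and TFF3 (−2.21, SE 0.20), and 1, WFDC2, rose (2.07, SE 0.11). That list passed camera (adjusted p = 0.00299), and had adjusted p = 0.189 with an estimated correlation.

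Luminal progenitor markers moved the other way. Of 17 tested, 12 rose and 4 fell, with rises of the keratin KRT15 (4.43, SE 0.15), the alveolar transcription factor ELF5 (2.27, SE 0.11) and the integrin ITGB8 (8.02, SE 0.24). The list had a camera adjusted p = 0.0323, and adjusted p = 0.264 with an estimated correlation. Its call was lost without SOX9OE replicate 1 (0.0536), with no low-count filter (0.114) and without genes shared between lists (0.108). Of 26 basal and myoepithelial markers, 15 rose and 8 fell, including ITGA6 (3.99, SE 0.08), CDH3 (2.84, SE 0.07) and LAMC2 (3.71, SE 0.14), and the list did not pass (camera adjusted p = 0.105), although it passed, as higher, with the DESeq2 Wald test (0.00783) and with no low-count filter (0.0161). Epithelial adhesion and junction genes rose in 18 of 32 cases and fell in 7 (camera adjusted p = 0.0427, and adjusted p = 0.329 with an estimated correlation). Examples were EHF (4.69, SE 0.08), the tight junction protein CLDN1 (4.77, SE 0.10) and the desmosomal cadherin DSC2 (4.63, SE 0.10). The junction list lost its call without ctrl replicate 2 (0.0560), ctrl replicate 3 (0.0552) or SOX9OE replicate 2 (0.0617), at CPM of at least 1 (0.0633), with protein-coding genes only (0.0583) and without genes shared between lists (0.0666). Mesenchymal transition genes split, with 10 of 22 higher and 9 lower (camera adjusted p = 0.809), with the matrix enzyme LOX (4.65, SE 0.10) and ITGAV (3.86, SE 0.06) up and CD44 down (−2.26, SE 0.10).

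Cartilage genes and neural crest and glial markers were higher in SOX9OE. Of 25 cartilage genes tested, 22 rose and 0 fell (camera adjusted p = 1.7e-07, and adjusted p = 0.112 with an estimated correlation). SOX6, a partner of SOX9 in cartilage, rose from 1.77 ± 0.133 to 283 ± 21.1 CPM, a log2 fold change of 7.32 (SE 0.10, adjusted p = 2.8e-17). The collagen COL2A1 (5.76, SE 0.16), the ubiquitin ligase WWP2 (3.19, SE 0.06) and the matrix protein MATN2 (2.78, SE 0.06) rose as well. Of 11 neural crest and glial markers, 9 rose and 1 fell (camera adjusted p = 0.00561, and adjusted p = 0.189 with an estimated correlation), with the myelin genes MPZ (7.30, SE 0.22) and PLP1 (6.91, SE 0.38) and the receptor ERBB3 (2.66, SE 0.10) among the rises. Other SOX family members went both ways, 4 of 8 higher and 4 lower (camera adjusted p = 0.369, but 5.2e-06, as higher, with the DESeq2 Wald test), and the 4 higher were SOX6, SOX8 (4.98, SE 0.17), SOX13 (2.91, SE 0.07) and SOX4 (1.39, SE 0.06). Hair follicle and intestinal SOX9-associated genes did too, 6 of 17 higher and 5 lower (camera adjusted p = 0.809), with SPP1 and KRT15 among the rises and GLI1 and ASCL2 (−2.35, SE 0.12) among the falls.

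Several signalling lists were higher. YAP and TEAD targets rose in 17 of 23 cases and fell in 4 (camera adjusted p = 0.00208, and adjusted p = 0.383 with an estimated correlation), led by the matricellular genes CCN2 (6.71, SE 0.12) and CCN1 (4.28, SE 0.07). TGF-beta and BMP response genes rose in 19 of 23 cases and fell in 2 (camera adjusted p = 0.000304, and adjusted p = 0.130 with an estimated correlation), including PMEPA1 (2.35, SE 0.08) and SMAD9 (2.60, SE 0.09). NF-kappaB targets rose in 13 of 17 cases and fell in 3 (camera adjusted p = 0.0130, and adjusted p = 0.616 with an estimated correlation), with NFKBIA (1.77, SE 0.10) and NFKB1 (1.36, SE 0.07) higher. AP-1 and immediate early genes rose in 14 of 20 cases and fell in 5 (camera adjusted p = 0.0187, and adjusted p = 0.391 with an estimated correlation), with JUN (2.67, SE 0.07) and FOS (3.53, SE 0.13) higher. Members of the MAPK feedback list were higher in 13 of 24 cases and lower in 7, with PHLDA1 (3.36, SE 0.09) and SPRED1 (2.16, SE 0.08) up and IER3 (−3.33, SE 0.12) and CCND1 (−2.88, SE 0.07) down, and the list did not pass (camera adjusted p = 0.298). Wnt targets, with 9 of 24 higher and 7 lower (camera adjusted p = 0.809), Notch genes, with 8 of 20 higher and 7 lower (0.939), and stem cell associated genes, with 9 of 18 higher and 8 lower (0.986), did not pass either. The Notch ligand DLL1 rose from 5.13 ± 0.346 to 38.3 ± 6.39 CPM and the Notch target NRARP fell (−3.85, SE 0.11). For the stem cell list the median and mean log2 fold changes were 0.00079 and 0.40 while camera placed it lower, and for the Wnt list camera placed it higher and fry lower.

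Cell cycle genes fell almost without exception. Of 30 G1/S genes, 29 fell and 1 rose (camera adjusted p = 1.7e-11), and of 30 G2/M genes 29 fell and 0 rose (camera adjusted p = 5.0e-12). With an estimated correlation these values were adjusted p = 0.314 and adjusted p = 0.383. The proliferation markers PCNA (−2.30, SE 0.07), MCM5 (−2.23, SE 0.06), PLK1 (−2.37, SE 0.07) and CCNA2 (−2.48, SE 0.08) fell by about the same amount. Of 26 p53 target and senescence genes, 13 fell and 8 rose, and the list did not pass (camera adjusted p = 0.132), although it passed, as lower, with the DESeq2 Wald test (0.0146) and with no low-count filter (0.0341). The inhibitor CDKN1A (−1.68, SE 0.06), GDF15 (−3.55, SE 0.11) and LMNB1 (−2.01, SE 0.06) were among the falls. Oxidative phosphorylation genes fell in 25 of 28 cases and rose in 0 (camera adjusted p = 1.1e-06, and adjusted p = 0.465 with an estimated correlation), for example ATP5F1B (−1.03, SE 0.06) and SDHB (−1.10, SE 0.07). Stress and unfolded protein response genes were higher in 14 of 26 cases and lower in 6 (camera adjusted p = 0.139), with DNAJC3 up (1.71, SE 0.07) and PHGDH down (−2.28, SE 0.07). Hypoxia and glycolysis genes, with 9 of 29 higher and 16 lower, had a median of −0.23 and a mean of 0.03 (camera adjusted p = 0.369, lower), with LDHA at −1.01 (SE 0.05) and KDM3A at 1.43 (SE 0.07). Cholesterol genes were higher in 7 of 24 cases and lower in 10 (camera adjusted p = 0.776), with DHCR24 up (1.64, SE 0.06) and PCSK9 down (−3.32, SE 0.12).

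**Figure D3:**
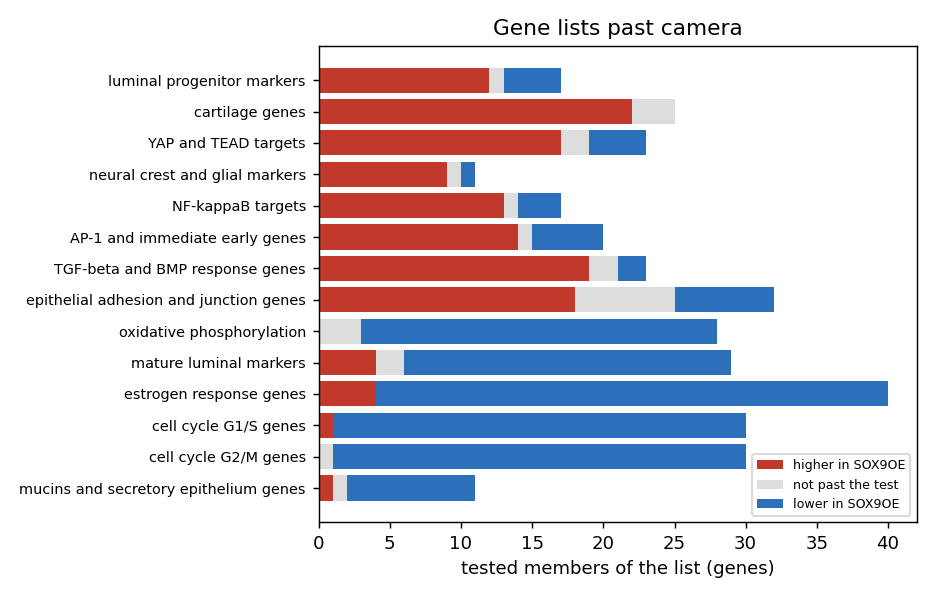
Number of tested members (horizontal axis, genes) that were higher, lower or not past the gene test in each gene list that passed camera with a preset correlation of 0.01. Of the 14 lists 8 were higher and 6 lower in SOX9OE, and 1, the estrogen response genes, also passed with an estimated correlation.

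Immune ligand and antigen presentation lists did not pass camera, although single members changed. Of 17 B7 family and other checkpoint ligands tested, 10 rose and 3 fell, and the list did not pass (camera adjusted p = 0.113). CD24, a ligand of an inhibitory macrophage receptor, rose from 44.6 ± 1.28 to 276 ± 15.4 CPM (log2 2.63, SE 0.06), HLA-E rose (1.27, SE 0.07) and the NK cell ligand NCR3LG1 fell (−1.60, SE 0.10). MHC class I presentation genes were higher in 10 of 20 cases and lower in 5 (camera adjusted p = 0.298), with the peptidase ERAP1 (1.90, SE 0.07) and TAPBP (1.25, SE 0.10) up and PSME2 (−1.25, SE 0.09) down. NK cell receptor ligands were higher in 11 of 17 cases and lower in 5 (camera adjusted p = 0.277), with CD58 (1.41, SE 0.09) and ULBP2 (1.73, SE 0.13) up. Interferon-stimulated genes were higher in 11 of 39 cases and lower in 15 (camera adjusted p = 0.369), among them IFI44 (−2.65, SE 0.11), BST2 (−2.13, SE 0.08) and IFI27 (−1.99, SE 0.09). Of 6 MHC class II genes 2 rose and 4 fell (camera adjusted p = 0.770), with CTSS up (4.70, SE 0.41) and CD74 down (−1.99, SE 0.32), a median of −1.16, a mean of 0.17, a lower direction in camera and a higher one in fry. Reads of HLA genes are shared between paralogs, so their values are uncertain. Cytokines and chemokines were higher in 11 of 21 cases and lower in 7 (camera adjusted p = 0.898), with a positive median (0.84) and mean (0.18) but a lower direction in fry. CXCL12 and IL20 fell most among its named members apart from IL24, whose exons overlap other genes over 41.6% of their length.

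Fibroblast and endothelial markers did not pass camera. Fibroblast markers were higher in 3 of 6 cases and lower in 2 (camera adjusted p = 0.809), where COL1A1 fell (−2.57, SE 0.11), COL3A1 rose (3.73, SE 0.63) and DCN, with 0 ctrl counts, was at least 7.99-fold higher at 0.489 ± 0.131 CPM. Endothelial markers were higher in 4 of 8 cases and lower in 1 (camera adjusted p = 0.718), with FLT1 (2.53, SE 0.13) and VWF (3.17, SE 0.41) up and ERG down (−1.71, SE 0.41). Only 4 of 15 leukocyte markers were expressed enough to test, so that list had no camera test, and 1 rose (ITGAM, 3.20, SE 0.69) and 2 fell. The falls were CD19 (−3.15, SE 0.28) and CSF1R (−1.62, SE 0.64, adjusted p = 0.0360). The CSF1R call was lost without ctrl replicate 1 (−1.34, adjusted p = 0.169), ctrl replicate 3 (0.0783), SOX9OE replicate 2 (0.1002) or SOX9OE replicate 3 (0.120). Across all lists, 14 of 34 passed camera, 1 with an estimated correlation and 28 by fry. Member counts adjusted over the list alone equalled those adjusted over all genes except for 1 more fall each in the MAPK, G2/M and p53 lists (8, 30 and 14).

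The ChIP comparison asked where SOX9 was bound in SOX9OE cells. Most bound sites appeared in both lists. Of the 12207 peaks called over ctrl SOX9 ChIP, 9094 (74.5%, 73.7 to 75.3) overlapped a peak called over input, and 9118 (82.3%) of the over-input peaks overlapped the other list, against a median of 23 and at most 43 in shuffled peaks. Both lists rest on the same SOX9OE ChIP libraries, so the overlap does not measure agreement between replicates. Summits of over-input peaks lay in introns in 58.7% of cases, between genes in 31.6% and in exons in 9.64%. Within 1 kb of a TSS lay 11.4% (10.8 to 12.02), against 3.78% of random positions. The median q-value was modest, with −log10 q at 2.03 for over-input and 2.01 for over-control peaks.

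At VTCN1, whose TSS lies at chromosome 1 position 117210960 (hg38, minus strand), 6 over-input peaks had their summit within 100 kb. An intronic peak at 117209089 to 117209473 had its summit 1622 bp inside the gene, with a signal value of 608 that exceeded 96.7% of the list. A stronger intronic peak at 117180300 to 117180741 lay 30515 bp inside the gene (signal 861), and a weaker one at 117176422 to 117176640 lay 34426 bp inside (signal 82.7) and was called over input only. Upstream, between genes, summits lay at −33563, −45497 and −49973 bp from the TSS, with signal values of 146, 25.2 and 374. The other 5 sites were also in the list called over ctrl SOX9 ChIP. At SOX9, 1 peak at chromosome 17, 72057665 to 72058313, lay at −62976 bp from the TSS in an intron of SOX9-AS1 (signal 944), and 0 peaks overlapped the SOX9 gene in either list.

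**Figure D4:**
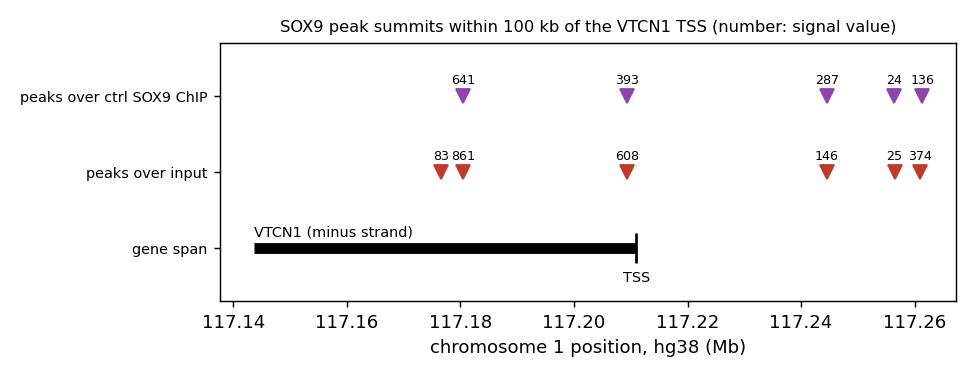
Summits of SOX9 peaks within 100 kb of the VTCN1 TSS on chromosome 1 (horizontal axis, hg38, Mb), with the gene span and a line of summits for each peak list, each labelled with its signal value. The 6 over-input summits include 3 inside the gene, 5 of the 6 sites have a counterpart in the list called over ctrl SOX9 ChIP, and the intronic peak with signal 861 is the strongest.

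The peaks with the highest signal values in both lists were not at the genes described so far. The order depends on the measure. By −log10 q, the BCAS3 peak named below (30.5) exceeded the chromosome 22 contig peak (21.5) in the over-input list, where the highest value was 32.95. The highest over-input signal values were 13694 on an unlocalised contig of chromosome 22, 12754 and 12732 at chromosome 21 positions 8388623 and 8205566 beside the microRNA genes MIR6724-3 and MIR6724-1, 11194 in an intron of BCAS3 on chromosome 17 (61312114 to 61313008) and 10712 at the start of chromosome 5 (10125 to 11725). In the list called over ctrl SOX9 ChIP, the same sites except the last stood in the top 5, joined by an intron of BRIP1 on chromosome 17 (61791870 to 61792867, signal 10858).

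Genes higher in SOX9OE lay near SOX9 peaks more often than unchanged genes, and lower genes less often. A summit lay within 10 kb of the TSS in 1387 of 6418 higher genes (21.6%), 821 of 6582 genes not past the threshold (12.5%) and 696 of 6259 lower genes (11.1%). With expression level and gene span as covariates, the odds ratio was 1.75 (95% interval 1.58 to 1.94) for higher genes and 0.673 (0.598 to 0.757) for lower genes, both against genes not past the threshold, and 2.36 (2.13 to 2.62) for higher against lower genes. Among the higher genes with a peak were IGFBP7, a secreted growth factor binding protein (log2 7.46, SE 0.10, from 1.69 ± 0.206 to 299 ± 16.5 CPM; summit 5305 bp inside the gene), PMP2 (summit at −480 bp, 81447919 on chromosome 8), the chondroitin sulfotransferase CHST11 (log2 5.77, SE 0.09) and the kinase FYN (log2 5.63, SE 0.09). SPRING1 (log2 4.45, SE 0.07), AADAT (3.99, SE 0.06), C3orf70 (4.56, SE 0.08) and the non-coding LINC00511 (5.89, SE 0.08) completed the 8 named. The peak nearest the TSS had a signal below the list median of 70.7 for CHST11 (15.3) and AADAT (27.7), and above it for the rest of the 8. Lower genes with a peak included PREX1 (−3.09, SE 0.08), whose peak had a signal of 11.7 and was called over input only, FGFR4 (−2.14, SE 0.07), the mitotic kinase AURKA (−2.19, SE 0.07) and thymidine kinase TK1 (−2.23, SE 0.07). The nearest peaks of FGFR4 (69.6), AURKA (29.1) and TK1 (50.3) also had signals below the list median. Of the other lower genes picked by the rule, PHGDH (22.4) and ASPM (13.6) lay below it, and RUVBL1 (135) and ARMT1 (150) above. The share rose with fold, from 3.42% of 234 genes below −4 to 31.4% of 557 genes above 4 on the log2 scale. Genes are not independent replicates, so these intervals are descriptive, and a summit within 10 kb does not assign a peak to a gene.

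**Figure D5:**
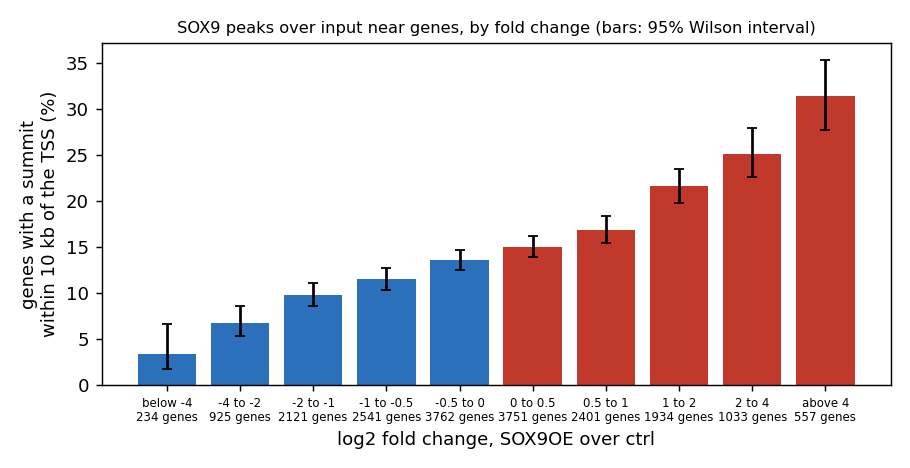
Share of tested genes (percent) with an over-input SOX9 peak summit within 10 kb of the TSS, by log2 fold change of SOX9OE over ctrl, with 95% Wilson intervals as bars. The share runs from 3.42% below −4 to 31.4% above 4.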

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

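The removal of length trends and the peak tests with a neighbourhood term or without chromosomes 17 and 20 were chosen after the data were seen. The log2 fold changes of SOX9 (6.82 to 7.09) and VTCN1 (6.06 to 6.69) stayed past the threshold under every scaling, test, filter, left-out library and the removal of length trends. Counts of genes higher in SOX9OE ran from 6136 to 6371 and lower from 5881 to 6215 over the left-out libraries. Against a fold of 1.5 with glmTreat they were 3704 and 3499, because the test excludes small changes. Of the named genes 0 reversed, and calls were lost for CSF1R in 7 settings and for MOBP in limma-voom. Lists past camera numbered 17 with DESeq2, which added the basal, SOX and p53 lists, 15 with no filter, 11 without genes shared between lists and 13 to 14 over the left-out libraries. They numbered 1 with an estimated correlation and 28 with fry, which compares no list with other genes. The luminal progenitor (−0.042), mucin (−0.037), neural crest (−0.025) and TGF-beta (−0.0058) lists had estimated correlations below the preset 0.01 and still lost their calls. The estrogen response list (−0.013) kept its call. For the lists below 0.01 these values argue against a higher correlation between genes as the cause of the loss. When camera estimates the correlation it also uses fewer degrees of freedom, those left by the libraries rather than by the genes. Neither this difference nor any other cause was tested.

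The direction of lists that had not passed camera reversed in the following cases, given as adjusted p, and the cause was not tested. With DESeq2, MHC class II (0.950), cytokines (0.234), Wnt (0.440) and fibroblast markers (0.440) turned, and with fry MHC class II (0.420), cytokines (0.000194) and Wnt (0.0144). Cytokines also turned at CPM of at least 1 (0.894), and hair follicle and intestinal genes without shared genes (0.926). The stem cell list turned with limma-voom (0.935), with no filter (0.873), with protein-coding genes only (0.999) and with each left-out library (0.846 to 0.994). Over the left-out libraries the values ran from 0.875 to 0.994 for Notch genes, which turned without ctrl replicate 2 or SOX9OE replicate 1, from 0.741 to 0.994 for fibroblast markers, which turned without SOX9OE replicate 3, and from 0.472 to 0.904 for endothelial markers, which turned without SOX9OE replicate 1. At CPM of at least 1, and without shared genes, 1 list each had too few members for a value.

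The replicate numbers of the sample titles gave no clear sign of pairing. Deviations from the group mean correlated at only 0.022, 0.010 and 0.054 for equal numbers, and at −0.049 to 0.028 for unequal ones. Ctrl replicate 1 correlated best with SOX9OE replicate 2 (0.028), but ctrl replicates 2 and 3 each correlated best with the same number. The deposited file names number the same libraries 1, 3 and 4 in ctrl and 1, 2 and 4 in SOX9OE, so the replicates titled 2 share no number there. With the number as a block, 6362 genes were higher, 6207 lower and 13 lists passed, the junction list had adjusted p = 0.0625, CSF1R 0.0643, and the stem cell list turned (0.955).

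For peaks, the upper 50% by signal held by construction 5538 over-input and 6104 over-control peaks. Overlap was 66.2% when 50% of both peaks had to be shared and 66.7% for summits within 100 bp, both stricter rules. The share within 1 kb of a TSS was 7.30% for protein-coding genes only, which are fewer, and 8.60% in the upper 50% by signal, where the cause was not tested. The odds ratio for higher genes stayed above 1 in each window, list and threshold tried, lowest at 1.19 for summits within 1 kb, and that for lower genes stayed below 1 over all settings (0.576 at a fold of at least 2 to 0.878 without covariates). Both motif shares, and their alternatives in window, motif length and peak threshold, were not run for lack of a genome sequence. Depth limits genes near the floor of 3 counts per library, 0.0592 to 0.0796 CPM.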

Other observations

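The gene families in this and the next paragraph, the ranking of segments by peak signal and the use of the peak test fixed beforehand to weigh gene span and expression level were chosen after the results were seen. For the other tests the deciding values were not known beforehand, although the length trend, the medians of genome segments and the strongest peaks were. The families were chosen on the values tested here, so their p-values, taken without members that stood in a list fixed beforehand or were named by rule, are only descriptive. Enzymes and transporters of glycosaminoglycan synthesis rose in 36 of 47 cases and fell in 3, and without such members rose in 33 of 44 and fell in 3 (camera adjusted p = 3.2e-07, and adjusted p = 0.0974 with an estimated correlation). They included CHST11 (log2 5.77, SE 0.09), the heparan sulfate glycosyltransferase EXTL1 (5.43, SE 0.11), UGDH, which makes the shared sugar precursor (3.07, SE 0.06), and PAPSS1, which makes the sulfate donor (2.73, SE 0.06). HAS2, a hyaluronan synthase, fell (−3.25, SE 0.26). Myelin-associated genes rose in 14 of 19 cases and fell in 1, and without PMP2, MOBP, MPZ and PLP1 in 10 of 15 and 1 (camera adjusted p = 0.00227, and adjusted p = 0.0974 with an estimated correlation), with CNP (3.51, SE 0.07), PMP22 (5.32, SE 0.22) and ERMN (6.48, SE 0.30) up and MAG down (−4.64, SE 0.51). Integrin subunits were higher in 12 of 20 cases and lower in 7, but without such members in 4 of 12 and 7 (camera adjusted p = 0.726), and laminin chains were higher in 7 of 10 and lower in 3, without such members in 5 of 7 and 2 (camera adjusted p = 0.103), with LAMA4 (7.69, SE 0.21) and LAMB1 (3.58, SE 0.08) up and LAMC3 down (−3.25, SE 0.24).

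All 74 cytosolic ribosomal protein genes tested were lower, from −1.43 for RPS2, whose exons overlap other genes over 25.9% of their length, to −0.28 for RPL15 (camera adjusted p = 8.7e-16, and adjusted p = 0.197 with an estimated correlation). Of 27 ribosome biogenesis factors 26 fell, including FBL (−2.19, SE 0.07) and NOLC1 (−1.94, SE 0.06), and 0 rose (camera adjusted p = 1.4e-10, and adjusted p = 0.0974 with an estimated correlation). Nucleotide and one-carbon synthesis enzymes fell in 30 of 44 cases and rose in 7, and without such members fell in 26 of 38 and rose in 5 (camera adjusted p = 2.6e-05, and adjusted p = 0.05001 with an estimated correlation), with PAICS (−2.57, SE 0.06) and MTHFD1 (−2.37, SE 0.06) down and MTHFD1L up (1.31, SE 0.06). Paralogs and processed pseudogenes share sequence with many ribosomal protein genes, so the size of those falls is uncertain.

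The first pattern weighed is that most tested genes differed between the lines. When SOX9 and the 20 genes with most counts were left out of the scaling, 99.3% of the calls kept their direction and threshold. TMM already trims extreme genes, so this test could change little and does not decide on a scaling cause. With length and span trends removed, 88.9% of the calls kept both, though 220 calls then reversed. That argues against a length bias as the whole cause. Subtracting the median change of each 10 Mb segment left 89.3% of the 6191 changes of at least 2-fold at that size. That argues against copy-number differences over such segments as the main cause of these larger changes. The rest of the 12677 calls was not tested, so copy number is not decided for smaller changes. Segment medians also varied more (SD 0.270) than with shuffled genes (at most 0.226), so some regional effect stands. The 10 splits of the 6 libraries are too few for a share under 0.05; the real split, 1 of 10, gave 12677 genes and the highest of the other 9 gave 0 in edgeR (52 to 111 at an unadjusted p under 0.05, at most 1 in DESeq2 and 0 in limma-voom), and for lists 14 against 11, but each other split mixes both lines in both groups. A response to SOX9 may underlie the changes, but how the lines were derived, RNA content per cell and clonal differences remain open and were not tested.

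The second pattern is that genes higher in SOX9OE lay near SOX9 peaks more often. The odds ratio was 1.75 with gene span and expression level as covariates, 1.71 with the number of peaks 100 kb to 1 Mb away added, and 1.79 without genes of chromosomes 17 and 20. Each interval stayed above 1, which argues against gene span, the density of surrounding peaks and the genes of chromosomes 17 and 20 as the whole cause. The expression level used was the mean over both groups, whereas the peaks come from SOX9OE cells. Level in SOX9OE cells was not a covariate, so the model does not decide on expression level. A candidate explanation is that SOX9 acts on part of these genes directly. Chromatin that is more open at active genes, and so yields more ChIP signal, was not tested and stays open.

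The third pattern is that the peaks with the highest signal values lay beside the MIR6724 genes, which sit in ribosomal DNA repeats, and in segments of chromosomes 17 and 20. The signal value is an area, and peak width was not taken into account. In the 5 Mb segments of chromosomes 17 and 20 that hold a top 12 peak, the 195 other over-input peaks had a median signal 2.87 times that of all peaks (203 against 70.7), with 2.54 for chromosome 17 from 60 to 65 Mb, 5.56 for chromosome 20 from 50 to 55 Mb and 1.85 from 55 to 60 Mb. Among 430 segments with at least 10 peaks besides the top 12, these 3 ranked 8, 3 and 19 by median signal and 14 reached 2 times that of all peaks; the highest (679) was an unplaced contig, and the segment of the top 12 peak on chromosome X ranked 257 (0.879 times). This is consistent with extra copies of whole segments, which both 17q23 and 20q13 carry in MCF-7 cells, as part of the cause on those 2 chromosomes, but the segment of the chromosome X peak shows no such rise. Repeated sequence at the ribosomal DNA and at the chromosome 5 end was not tested, nor was any biological explanation.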
